A study of Trametes elegans with 15 samples.

How the data were processed

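The samples were mycelium of *Trametes elegans* (named *Artolenzites elegans* in the sample titles), grown for 3 days on maltose or on cellulose, wheat straw, pine or aspen with maltose. Per the labels' protocols, cDNA made from poly A RNA was sequenced as paired-end reads on an Illumina HiSeq 2500. The submitters' processing notes name TopHat2, HTSeq and DESeq 1.5 without saying what each was used for. The genome build and annotation version are not given in the sources used here, and the file header names the JGI MycoCosm portal of this species. Reads from plant material, near-identical gene copies and overlapping genes could not be examined, since the table holds only gene numbers and levels, and the strand setting of the counting is not given in the sources used here.

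The authors deposited 1 table of 949 genes with 5 value columns, each headed normalised log2 read count per the file headers, 1 per medium. The values are on a log2 scale from 0 to 17.27. Neither the labels nor the header says how libraries were combined into 1 value, how the genes were selected or which pseudocount was used. No reference genome or annotation was used, so no positions or gene names are given. The header and the labels do not define the gene numbers beyond the portal.

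The design fixed before the data were examined named limma on log2 values per library, and provided that, with 1 value per substrate, no test would be made and genes would be counted by size. The table holds 1 value per medium. After it was seen, 4356 of the 4745 deposited log2 values decoded uniquely as the mean over K libraries of log2(reads x factor + 1). In that form the reads are whole and each library has its own factor. Whole reads were therefore recovered, and the planned limma test was run on them as the main result. This choice was made after the data were seen, so the counts by size that the design provided are printed beside every test.

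The recovery searched for factors under which low values decode to whole reads, then searched each value for sets of whole reads. A set was accepted where it met the deposited value within 4e-14 on the natural log scale below level 10 and within 2e-13 from level 10. These tolerances, the level limit and the search ranges were settled over several versions, from the residuals and the run time. Of 20 low values tried per medium, 20 decoded with K = 3 on maltose, cellulose, pine and aspen and 0 with K = 2. On wheat straw 20 decoded with K = 2 and 1 with K = 3, so this column rests on 2 libraries, although the labels list 3 samples. The third straw sample is not analysed here. Of the 4745 deposited values, 4356 gave exactly 1 set of whole reads. Below level 9 this held for 2564 of 2564 values, and 0 of as many decoy values, shifted by 1e-06, gave a set. From level 9 to 13 it held for 1685 of 1741 values, while 48 gave several sets and 8 gave none, and 42 decoys gave a set, so a few of these read sets can be wrong. The 333 values at 13 or more in the media with 3 libraries were not searched, since too many sets match. In simulated tables, which left out the higher genes, the true reads were found for all 745 genes simulated after pine and all 689 genes simulated after straw. The simulation therefore does not test recovery at levels 11 to 13, where most of the decoys with a set lay. Several of the genes named below lie at these levels.

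In the recovered libraries 1 read was worth 0.878 to 1.20 normalised counts. Reads over the genes recovered in a library ranged from 598587 to 3289916, where straw counts 948 genes and includes the highest ones. Recovered libraries have no replicate number, and are named a, b and c within a medium only by the order of their factors. Read counts of replicate libraries differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 3.86 to 96.6, so none was counted as a duplicate. The largest value was that of the straw pair. It covers 942 genes, with the highest ones among them, against 827 to 844 genes for the other pairs, so it is not directly comparable.

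Limma 3.58.1 in R 4.3.3 was fitted to log2(reads x factor + 1) of the 14 libraries, with a mean per medium, an intensity trend and no covariates. Each comparison tested genes recovered in both media, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. The 10 comparisons were the 4 solids against maltose and the 6 pairs of solids. A call needs an adjusted p under 0.05 and an absolute log2 difference of at least 1. A moderated F test over the 5 media used the 777 genes recovered in all 14 libraries. In a simulation of pine against maltose over 949 genes, limma called 100 of 100 genes changed by 1.5 on the log2 scale and 1 of 749 unchanged genes. For straw against maltose the simulation gave 99 of 100 and 0 of 749, and for pine against cellulose 99 of 100 and 0 of 749. It gave every gene and medium the same dispersion of 0.00538, a median over maltose genes of higher level. It therefore does not show how limma performs for genes with more spread, such as 677373 on cellulose (SD 1.46), or for the straw pair. Overlaps and correlations between comparisons with maltose were set beside 20 simulations in which no group changed. These drew every library, maltose included, around the mean of each gene with the spread that limma estimated. Within a simulation all comparisons shared the same simulated maltose libraries.

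Genes were named by a rule fixed before the data were examined. It takes those with the largest rise and the largest fall among called genes whose libraries do not overlap between the 2 media. As genes are bare numbers, the rule limits them to 2 in each direction per comparison, with the same limit for the highest genes of each medium. Genes not recovered in both media of a comparison could not be called. The largest change of such a gene in each direction is given by size where it exceeds one of those named. Intervals and limits that start from reads cover counting error only. Where a medium held 1 to 3 reads of a gene, the ratio of normalised reads is given with an exact 95% interval. Zero reads were set against a limit of 3 reads over the libraries of the medium.

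Alternatives were other scalings (centring on the library median, quantile normalisation, centring on the median difference from the gene means), a filter on low levels, pseudocounts of 0.5 and 5, other minimum differences, limma without trend and with array weights, fits with only the libraries compared, and leaving out each library. The lists of enzyme families fixed in the design were not tested, because the table carries no annotation. Scripts ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.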

Results

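Transcript levels of the white-rot fungus *Trametes elegans*, strain BRFM 1663, were compared after 3 days of shaken culture at 30 °C in 5 media. The labels list 15 mycelium samples, 3 per medium. The control medium held maltose, a soluble disaccharide, at 20 g/l. The other 4 media held 15 g/l of a solid substrate with maltose. The solids were microcrystalline cellulose (Avicel), wheat straw, pine (a softwood) and aspen (a hardwood). The labels give 2.5 g/l of maltose beside cellulose, straw and pine, and the amount printed for aspen cannot be read. Comparisons of cellulose, straw and pine with the control medium therefore differ both in the solid and in the amount of maltose. For aspen a difference in maltose is not known, either from the control medium or from the other solids. The deposited table lists 949 genes, each with 1 normalised log2 read count per medium, and does not say how these genes were chosen. It identifies genes by number and does not pair the numbers with names or functions, so the enzyme families fixed in advance could not be matched and genes are given here by number.

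Whole reads per library were recovered from the decimals of the deposited values for 14 libraries: 3 each on maltose, cellulose, pine and aspen, and 2 on wheat straw. The deposited straw value is a mean over 2 libraries, although the labels list 3. The labels do not say that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. Each SE and p-value uses 1 spread per gene, pooled over the media and moderated by limma. For straw, with 2 libraries, that spread rests mostly on the other media. Over the 777 genes recovered in every library, the reads ranged from 409047 in a pine library to 1149683 in a straw library. These reads are part of each library and not its depth, which is not known. Over the same 777 genes, the median SD between libraries was 0.16 on maltose, 0.17 on cellulose, 0.13 on straw, 0.16 on pine and 0.16 on aspen, on the log2 scale. The straw value comes from 2 libraries and is not directly comparable with the others. Levels below are the authors' deposited values, as log2(normalised read count + 1), and their SD and n are those of the recovered libraries. A fold on this scale understates the change of genes with few reads.

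Libraries of the same medium lay close together and those of different media lay apart. The root mean square difference between libraries was 0.39 to 0.43 within a medium. Between media it ranged from 1.37 for pine and aspen to 2.39 for maltose and straw. All 14 libraries had their nearest neighbour in their own medium. The genes with the highest level were 826215 on maltose (15.86), 850433 on cellulose (16.83) and aspen (16.34), 802227 on straw (16.97) and 873101 on pine (17.27). Gene 826215 lay between 15.61 and 15.92 in all 5 media, whereas 802227 lay at 6.47 on maltose and 873101 at 10.77.

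**Figure D1:**
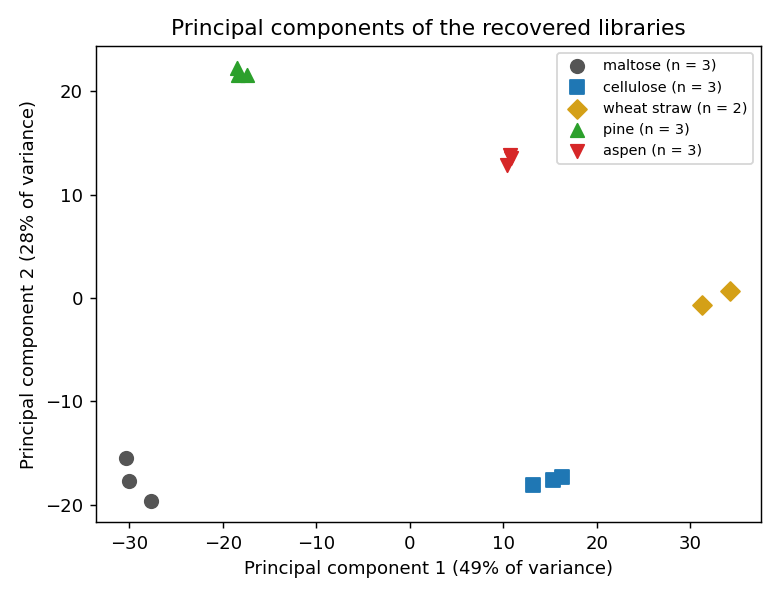
Principal components 1 (49% of variance) and 2 (28% of variance) of the log2 values of 777 genes, with each point a recovered library (n = 3 per medium, n = 2 for wheat straw). The 5 media form separate groups, with maltose and pine to the left of 0 on component 1 and cellulose, aspen and straw to the right.

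A gene was called changed where limma's adjusted p was under 0.05 and the log2 difference was at least 1. How many called genes were higher and how many lower depended on how libraries were scaled, because the median level of the recovered genes differed between media. Relative to the mean of all libraries it lay at -0.42 on maltose, 0.19 on cellulose, 0.54 on straw, -0.34 on pine and 0.21 on aspen. Over all 949 listed genes the deposited medians were 8.10, 8.86, 9.21, 8.11 and 8.91, in the same order. Splits are given first as the authors scaled the values, then after centring each library on its own median and after quantile normalisation. Median centring lowered every difference from maltose by 0.61 on cellulose, 0.96 on straw and 0.63 on aspen. The most frequent difference over all listed genes lay at 0.08, -0.03 and 0.15 there. Such centring therefore moves genes near 0 towards a fall of 1, and can by itself add genes called lower. Levels of 13 or more were recovered on straw, for 107 genes, but in no other medium. Quantile normalisation therefore matches unlike ranges in the straw comparisons, and its straw values carry that limit. Centring each library on its median difference from the gene means, chosen after the data were seen, is given where it moved the split by more than 10 percentage points, and for cellulose against maltose. Every tested gene named in a comparison below kept its call and direction under all of these scalings, though the size of its change moved with them. These genes were picked for the largest changes, so this does not speak for other called genes.

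On crystalline cellulose, gene 812358 rose from 2.74 ± 0.16 (SD, n = 3) on maltose to 11.77 ± 0.07 (SD, n = 3), a 521-fold rise from 19 reads over the maltose libraries. Gene 837354 rose 307-fold, from 3.92 ± 0.30 to 12.18 ± 0.33. Gene 811231 fell from 10.07 ± 0.15 to 4.17 ± 0.47, and gene 767105 fell from 11.33 ± 0.37 to 6.25 ± 0.48. Of the 814 genes tested, 225 rose and 94 fell, and the median changes of these were 2.11 and -1.66. The log2 differences were 9.03 (SE 0.14, limma adjusted p = 1.89e-16) for 812358 and 8.26 (SE 0.21, 8.69e-14) for 837354. They were -5.90 (SE 0.25, 1.62e-11) for 811231 and -5.08 (SE 0.23, 3.38e-11) for 767105. With a pseudocount of 5 in place of 1, the rise of 812358 was 8.35. The called genes were 70.5% higher as deposited, but 42% after median centring and 47.2% after quantile normalisation, so the majority turned under these 2 scalings but not after centring on the median difference (63%). By size alone, over all 949 genes, 268 were higher and 116 lower by at least 1. Genes 802227, at 15.85 on cellulose, and 165303, at 14.87 on maltose, were too high there to be tested. They differed by 9.38 and -6.26, more than the tested genes named above.

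On wheat straw, a grass lignocellulose, gene 848748 rose from 4.82 ± 0.24 (SD, n = 3) on maltose to 15.34 ± 0.77 (SD, n = 2), a 1468-fold rise. Gene 802227, the highest of all genes on straw, rose 1442-fold, from 6.47 ± 0.21 to 16.97 ± 0.31. Gene 809348 fell from 11.79 ± 0.49 to 2.99 ± 0.95, and gene 6623 fell from 11.02 ± 0.20 to 5.84 ± 0.13. Of the 853 genes tested, 297 rose and 102 fell, the most calls (399) of the 10 comparisons, and 193 rose at least 4-fold. By limma, the log2 differences were 10.52 (SE 0.26, limma adjusted p = 3.53e-14) for 848748 and 10.49 (SE 0.22, 3.39e-12) for 802227. They were -8.79 (SE 0.39, 2.06e-11) for 809348 and -5.17 (SE 0.15, 1.27e-13) for 6623. Straw libraries a and b held 60252 and 26808 reads of 848748, and 148389 and 104012 of 802227. The SE of 0.26 for 848748, pooled over the media, does not reflect its straw SD of 0.77. After quantile normalisation the rises were 8.18 for 848748 and 6.53 for 802227, and without straw library a or b the change of 809348, which held 15 reads on straw, was -8.13 or -9.46. For that gene a pseudocount of 5 gave -8.17 and quantile normalisation -9.54. Of the called genes, 74.4% were higher as deposited, but 39.3% after median centring, 46.8% after quantile normalisation and 63.2% after centring on the median difference. By size alone, 306 of the 949 genes were higher and 128 lower. Gene 165303, not tested, differed by -7.05, a larger fall than that of 6623.

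On pine, gene 677373 rose from 3.55 ± 0.40 (SD, n = 3) on maltose to 11.74 ± 0.20 (SD, n = 3), a 291-fold rise. Gene 807754 rose 55.5-fold, from 4.15 ± 0.29 to 9.95 ± 0.14. Gene 809348 fell from 11.79 ± 0.49 to 4.24 ± 0.35, as it did on straw, and gene 911219 fell from 12.53 ± 0.27 to 5.75 ± 0.46. Of the 826 genes tested, 168 rose and 147 fell, so the changes were nearly balanced. Fitted log2 differences were 8.18 (SE 0.48, limma adjusted p = 1.03e-09) for 677373 and 5.80 (SE 0.15, 1.86e-13) for 807754. They were -7.55 (SE 0.35, 8.16e-11) for 809348 and -6.78 (SE 0.19, 5.16e-13) for 911219. As deposited, 53.3% of the called genes were higher, with 49.7% after median centring and 53.6% after quantile normalisation. By size alone, 191 of the 949 genes were higher and 180 lower. Genes 873101 and 165303, not tested, differed by 6.50 and -7.20, more than 807754 and 911219.

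On aspen, gene 812358 rose from 2.74 ± 0.16 (SD, n = 3) on maltose to 11.80 ± 0.19 (SD, n = 3), close to its level on cellulose. Gene 237425 rose 169-fold, from 5.08 ± 0.19 to 12.49 ± 0.21. Gene 809348 fell from 11.79 ± 0.49 to 2.83 ± 0.41, and gene 811181 fell from 8.64 ± 0.75 to 3.35 ± 0.28. Of the 816 genes tested, 240 rose and 108 fell, with median changes of 2.01 and -1.77. The log2 differences were 9.06 (SE 0.14, limma adjusted p = 3.15e-16) for 812358 and 7.40 (SE 0.29, 6.07e-12) for 237425. They were -8.96 (SE 0.35, 6.48e-12) for 809348 and -5.29 (SE 0.33, 1.4e-09) for 811181. A pseudocount of 5 gave 8.38 for 812358 and -8.31 for 809348, and quantile normalisation gave -5.96 for 811181. The called genes were 69% higher as deposited, but 41.9% after median centring, 46.9% after quantile normalisation and 55.4% after centring on the median difference. By size alone, 280 of the 949 genes were higher and 140 lower. Gene 165303, not tested, differed by -6.415, a larger fall than that of 811181.

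**Figure D2:**
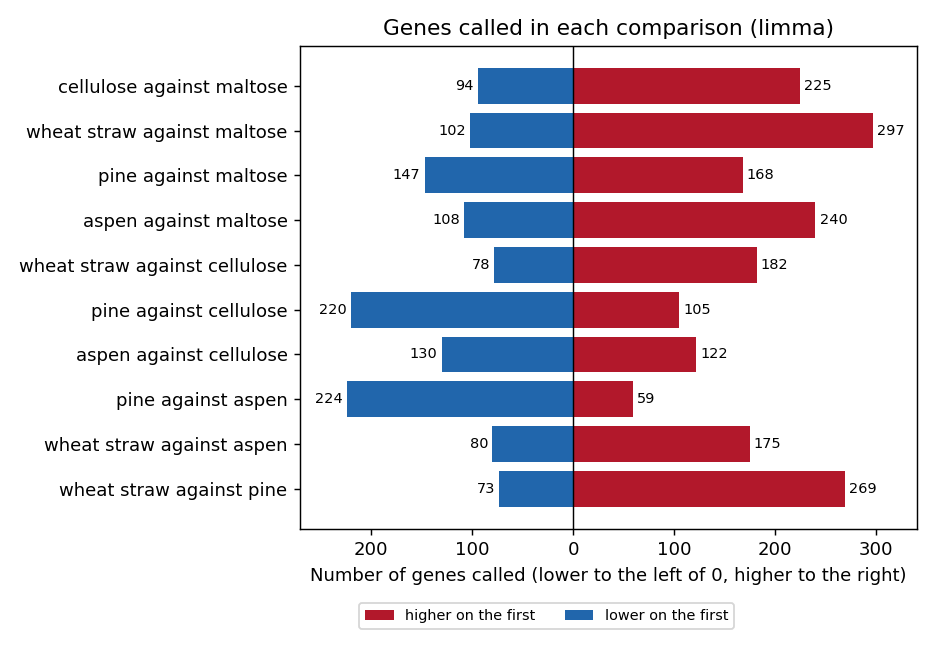
Number of genes called in each of the 10 comparisons (limma adjusted p under 0.05 and a log2 difference of at least 1), with bars to the right for genes higher on the first-named medium and to the left for genes lower on it. As deposited, straw against maltose has the longest bar to the right (297) and pine against aspen the longest to the left (224). Centring each library on its median turns the majority in every comparison except straw against cellulose and aspen against cellulose. Centring on the median difference from the gene means turns it in none.

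The changes against maltose were shared in part between the 4 solids. Of the 777 genes tested in every comparison, 66 rose on all 4 solids, 32 fell on all 4 and 260 were called on none. Genes that rose on 2 solids numbered 168 for straw and aspen, 163 for cellulose and straw, 144 for cellulose and aspen, 110 for pine and aspen, 96 for straw and pine, and 73 for cellulose and pine. Independent lists of these sizes share 71.2, 66.4, 59.7, 40.5, 45 and 37.7 genes. Genes that fell on 2 solids numbered 51 to 75 per pair, against 11.5 to 18.7 for independent lists. These numbers too moved with scaling: after median centring, 95 genes rose and 157 fell on both cellulose and straw, against 163 and 55 as deposited. On all 4 solids, 46 rose and 63 fell after median centring, and 53 rose and 56 fell after quantile normalisation. Simulated unchanged groups, set against maltose libraries that were simulated too, hold almost no calls by limma. They so shared 0, which gives no expected overlap for groups that changed. Across genes, which are not independent replicates, the changes correlated at Pearson's r of 0.794 for straw and aspen, 0.748 for pine and aspen, 0.741 for cellulose and straw and 0.709 for cellulose and aspen. The values were 0.496 for straw and pine and 0.406 for cellulose and pine. Simulated unchanged groups gave 0.434 to 0.492, since all comparisons in a simulation use the same simulated maltose libraries. Any real departure of the 3 maltose libraries is left out of the simulation. The covariances were 1.13 to 3.23, against 0.0233 to 0.0245 in the simulation. The 3 maltose libraries were too few to be split, and part of the overlap may come from sharing them.

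Genes that rose on cellulose were followed on the other solids. Of these 225 genes, 180 also rose on straw, 145 of the 209 tested rose on aspen, and 84 of the 219 tested rose on pine. The median change from maltose was 2.49 on straw, 1.96 on aspen and 0.66 on pine. The direct tests placed 143 of them lower and 15 higher on pine than on cellulose, 75 lower and 32 higher on aspen, and 41 lower and 81 higher on straw. These genes were chosen for a high value on cellulose, which favours lower values elsewhere.

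Straw, a whole plant tissue, was compared directly with cellulose. Gene 815362 was at 11.69 ± 0.94 (SD, n = 2) on straw and at 2.05 ± 0.70 (SD, n = 3) on cellulose, where its libraries held 10 reads in all. Gene 806789 was at 8.87 ± 0.41 on straw and at 1.77 ± 0.81 on cellulose, with 8 reads there. Gene 419214 was lower on straw, at 5.79 ± 0.13 against 12.74 ± 0.23, and so was gene 814979, at 3.70 ± 0.43 against 10.11 ± 1.03. Of the 844 genes tested, 182 were higher on straw and 78 lower. By limma, the log2 differences were 9.64 (SE 0.44, adjusted p = 2.5e-10), 7.09 (SE 0.63, 1.52e-07), -6.95 (SE 0.20, 1.53e-12) and -6.41 (SE 0.54, 9.4e-08), in the same order. Without straw library a or b the difference for 815362 was 8.97 or 10.30, and without cellulose library c that for 814979 was -7.00. A pseudocount of 5 gave 8.64 for 815362 and 5.95 for 806789. Of the called genes, 70% were higher as deposited, but 50.8% after median centring and 54.6% after quantile normalisation. By size alone, 197 of the 949 genes were higher and 105 lower.

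Pine was set against cellulose directly. Gene 677373 was at 11.74 ± 0.20 (SD, n = 3) on pine and at 3.77 ± 1.46 (SD, n = 3) on cellulose. Gene 769467 was 21.9-fold higher on pine, at 11.99 ± 0.19 against 7.54 ± 0.16. Gene 765849 was lower on pine, at 3.33 ± 0.64 against 11.70 ± 0.25, and so was gene 808587, at 2.16 ± 0.46 against 10.13 ± 0.17. Of the 812 genes tested, 105 were higher on pine and 220 lower. Fitted log2 differences were 7.97 (SE 0.48, limma adjusted p = 1.04e-09), 4.45 (SE 0.13, 5.05e-13), -8.37 (SE 0.30, 4.28e-12) and -7.97 (SE 0.27, 2.73e-12), in the same order. Without cellulose library c the difference for 677373 was 7.13. Quantile normalisation gave -7.67 for 765849 and -7.14 for 808587, and a pseudocount of 5 gave -7.04 for 808587, which held 10 reads on pine. As deposited, 32.3% of the called genes were higher on pine, but 57% after median centring, 57.3% after quantile normalisation and 42.9% after centring on the median difference, so the majority turned under the first 2 of these scalings. By size alone, 128 of the 949 genes were higher and 262 lower. Genes 873101 and 765709, not tested, differed by 5.45 and -9.17, more than 769467 and 765849.

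Between aspen and cellulose, gene 677373 was again higher on the wood, at 9.75 ± 0.16 (SD, n = 3) against 3.77 ± 1.46 (SD, n = 3). Gene 237425 was 24.4-fold higher on aspen, at 12.49 ± 0.21 against 7.88 ± 0.83. Gene 419214 was lower on aspen, at 6.62 ± 0.20 against 12.74 ± 0.23, and so was gene 620294, at 2.13 ± 0.38 against 8.10 ± 0.22. Of the 814 genes tested, 122 were higher on aspen and 130 lower. The log2 differences were 5.98 (SE 0.48, limma adjusted p = 6.86e-08), 4.61 (SE 0.29, 4.21e-09), -6.12 (SE 0.18, 1.82e-12) and -5.97 (SE 0.31, 4.91e-10), in the same order. Without cellulose library c the difference for 677373 was 5.14. A pseudocount of 5 gave -5.05 for 620294, which held 11 reads on aspen, and quantile normalisation gave 5.23 for 237425. The called genes were 48.4% higher as deposited, 46.7% after median centring and 50.8% after quantile normalisation. By size alone, 142 of the 949 genes were higher and 163 lower. Genes 775533 and 772128, not tested, differed by 5.52 and -7.02, more than 237425 and 419214.

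The softwood and the hardwood were compared directly as pine against aspen, where the amount of maltose may differ too. Gene 767105 was 9.85-fold higher on pine, at 10.53 ± 0.19 (SD, n = 3) against 7.23 ± 0.26 (SD, n = 3), and gene 769467 was 8.93-fold higher, at 11.99 ± 0.19 against 8.83 ± 0.15. Gene 808587 was lower on pine, at 2.16 ± 0.46 against 8.17 ± 0.55. Gene 804729 held 2 reads over the pine libraries and 208 over the aspen libraries, a ratio of 90.6 in favour of aspen (95% interval from counting error only, 24.8 to 753). Of the 827 genes tested, 59 were higher on pine and 224 lower. By limma, the log2 differences were 3.30 (SE 0.23, adjusted p = 8.48e-09) for 767105, 3.16 (SE 0.13, 5.25e-11) for 769467 and -6.01 (SE 0.27, 1.2e-10) for 808587. For 808587, a pseudocount of 5 gave -5.10 and quantile normalisation -5.23. Of the called genes, 20.8% were higher on pine as deposited, but 53.8% after median centring, 49.4% after quantile normalisation and 39.6% after centring on the median difference. By size alone, 79 of the 949 genes were higher and 251 lower.

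Straw and aspen, a grass and a hardwood, differed by 255 called genes, against 342 for straw and pine. Gene 808921 was at 11.95 ± 0.04 (SD, n = 2) on straw and at 4.24 ± 0.89 (SD, n = 3) on aspen. Gene 815362 was 83.4-fold higher on straw, at 11.69 ± 0.94 against 5.30 ± 0.27. Gene 814979 was lower on straw, at 3.70 ± 0.43 against 9.07 ± 0.23, and so was gene 814337, at 8.39 ± 0.05 against 12.16 ± 0.15. Of the 852 genes tested, 175 were higher on straw and 80 lower. Fitted log2 differences were 7.71 (SE 0.51, limma adjusted p = 1.02e-08), 6.38 (SE 0.44, 1.51e-08), -5.37 (SE 0.54, 6.47e-07) and -3.77 (SE 0.18, 4.06e-10), in the same order. The difference for 815362 was 5.72 without straw library a and 7.05 without library b, and that for 814337 was -4.72 after quantile normalisation. As deposited, 68.6% of the called genes were higher, but 49.6% after median centring and 48.3% after quantile normalisation. By size alone, 183 of the 949 genes were higher and 101 lower.

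Between straw and pine, gene 815362 was 479-fold higher on straw, at 11.69 ± 0.94 (SD, n = 2) against 2.78 ± 0.32 (SD, n = 3). Gene 804729 held 1796 reads over the straw libraries and 2 over the pine libraries, a ratio of 1290 (95% interval from counting error only, 356.5 to 10660). Gene 810634 was lower on straw, at 7.62 ± 0.35 against 12.05 ± 0.31, and so was gene 767105, at 6.27 ± 0.06 against 10.53 ± 0.19. Of the 857 genes tested, 269 were higher on straw and 73 lower. The log2 differences were 8.90 (SE 0.44, limma adjusted p = 1e-10) for 815362, -4.43 (SE 0.18, 1.17e-11) for 810634 and -4.26 (SE 0.25, 8.1e-10) for 767105. The difference for 815362, which held 17 reads on pine, was 8.24 without straw library a and 9.57 without library b. With a pseudocount of 5 it was 8.24 and after quantile normalisation 7.98, and that for 810634 was -5.16 after quantile normalisation. The called genes were 78.7% higher as deposited, but 38.1% after median centring, 39.9% after quantile normalisation and 65.2% after centring on the median difference. By size alone, 279 of the 949 genes were higher and 94 lower.

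Over the 5 media together, 720 of the 777 genes (92.7%) differed by limma's F test at an adjusted p under 0.05. Genes called higher in 1 medium than in each of the other 4 numbered 73 on straw, 32 on maltose, 27 on cellulose, 16 on pine and 11 on aspen. Genes called lower than in each of the other 4 numbered 66 on maltose, 45 on pine, 9 on cellulose, 6 on straw and 2 on aspen. Genes at 13 or more on maltose, cellulose, pine or aspen could not enter these counts, whereas genes that high on straw could, which can favour straw. Among those left out were 165303 (14.87 on maltose, 7.67 to 8.60 elsewhere) and 772128 (15.96 on cellulose, 8.23 to 11.87 elsewhere). After median centring the counts on pine turned to 35 higher and 23 lower, those on maltose to 63 and 46, and those on straw became 55 and 24. Those on cellulose became 33 and 12, and those on aspen 12 and 5. Quantile normalisation gave 14 and 8 on aspen. Gene 807754 was lowest on maltose, at 4.15, against 9.91 to 10.90 elsewhere. Gene 811231 was highest on maltose, at 10.07, against 4.17 to 5.49 elsewhere. Gene 419214 reached 12.74 on cellulose and no more than 6.96 elsewhere, and gene 815362 reached 11.69 on straw and no more than 5.30 elsewhere. Gene 769467 stood at 11.99 on pine and at most 8.83 elsewhere, and gene 814337 at 12.16 on aspen and at most 9.93 elsewhere.

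**Figure D3:**
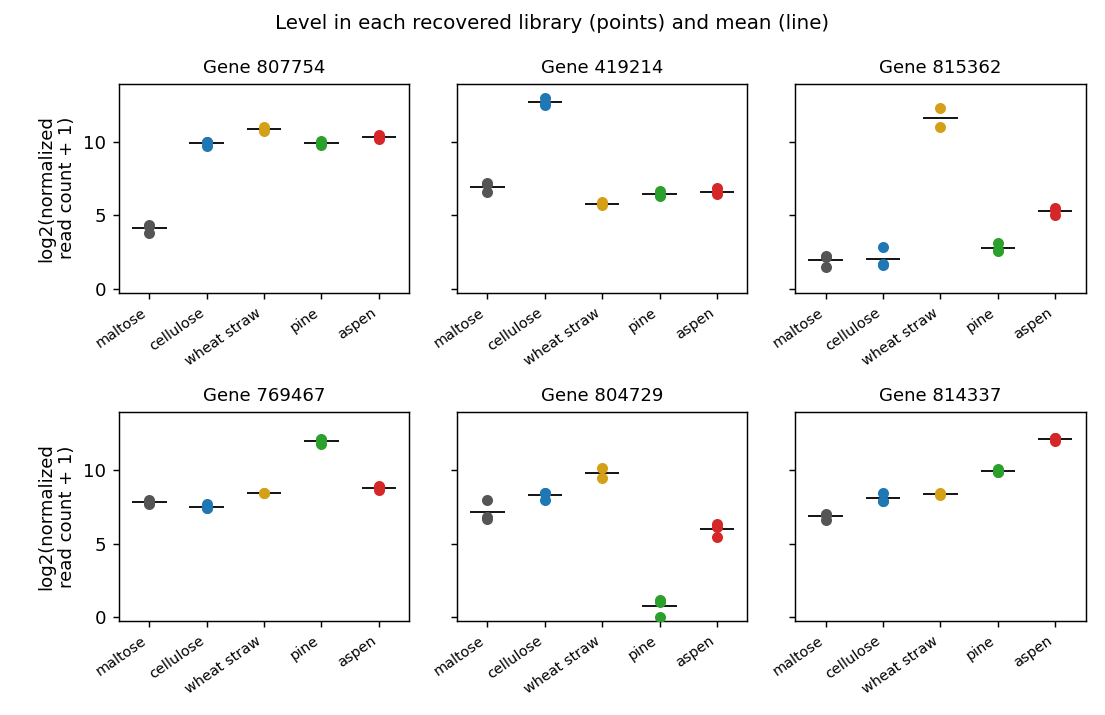
Levels of 6 named genes as log2(normalised read count + 1), with each point a recovered library and each line the mean of a medium (n = 3, n = 2 for wheat straw). Each gene has a medium that stands apart from the other 4: low on maltose for 807754, high on cellulose for 419214, high on straw for 815362, high on pine for 769467, low on pine for 804729 and high on aspen for 814337.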

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

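In this part, the test on reads was chosen after the results were seen, and the count of genes remaining after centring was restricted to the original genes afterwards; the other tests on opposite changes were written before.

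Genes changed in opposite directions against maltose on 2 solids, with a direct test between those solids that also passed limma's threshold, were found for each pair. There were 14 for cellulose and wheat straw, 7 higher on each. There were 33 for cellulose and pine, of which 28 rose on cellulose and fell on pine. There were 9 for cellulose and aspen, of which 7 rose on cellulose. There were 12 for straw and aspen, of which 10 rose on straw, and 10 for pine and aspen, all of which rose on aspen and fell on pine. There were 32 for straw and pine, of which 29 rose on straw and fell on pine.

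The straw and pine set was weighed further. The planned test of noise in genes with few reads does not decide, since 78.1% of the 32 genes lay among the upper 75% of listed genes by mean level, about the share of any genes. Counted by reads, 7 of the 32 had fewer than 30 reads over the libraries of maltose, straw or pine, which leaves noise open for those 7 and argues against it for the other 25. A fall on pine itself leaves few reads there, so few reads alone do not mark those 7 as noise. A difference of scaling between libraries would remove the pattern, but 27 of the 32 genes were still called in opposite directions after centring each library on its median (34 genes in all were, by that scaling). The difference between the substrates themselves stays open as a hypothesis, since the set was found and tested on the same libraries and the straw levels rest on 2 libraries.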

How the results depend on the processing

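Recovering reads and testing them, centring on the median difference from the gene means, and the fit without the straw libraries were chosen after the data were seen; the other alternatives were fixed before. No paired analysis was possible because the recovered libraries carry no replicate number. Count models on the recovered reads were not run, since the deposited values are log2 and the reads of the highest genes were not recovered. Enzyme family tests were not run for want of annotation, and weighting by node does not apply because the table lists genes. The 675 alternative values computed for the named genes kept their call and direction. These genes were picked for the largest changes, the smallest 3.16 as deposited, so this follows largely from the choice and does not speak for other genes. The filter on low levels removed some of the named genes, so it gave 27 of the 40 values. Numbers of called genes stayed within 1.5 times the main ones under the 3 scalings, the pseudocounts, the filter, limma without trend or with array weights, fits with only the libraries compared and leaving out each library, but the split between higher and lower moved with scaling and turned in some comparisons, as given beside them. Without a straw library the remaining one is assumed to vary like the other media. Leaving out a library gave, for example, 312 to 325 calls for cellulose against maltose and 391 to 402 for straw against maltose. Depth limits genes with few reads, and genes at 13 or more on the log2 scale in a medium with 3 libraries were not tested there.

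The minimum difference set the counts. With none, limma called 573, 618, 552 and 592 genes for cellulose, straw, pine and aspen against maltose, 493, 595 and 564 for straw, pine and aspen against cellulose, 568 for pine against aspen, 513 for straw against aspen and 594 for straw against pine. With a minimum of 2 it called, in the same order, 149, 229, 128, 164, 110, 149, 85, 115, 109 and 187. By size of the deposited values, a minimum of 0.5 gave 598 for cellulose against maltose, 595 for pine against maltose, 508, 628 and 563 for straw, pine and aspen against cellulose, 595 for pine against aspen, 536 for straw against aspen and 620 for straw against pine. A minimum of 2 gave, in the first order, 188, 243, 158, 205, 124, 188, 113, 128, 113 and 191. These follow from the minimum itself. By size, straw against pine gave 582 after centring each substrate on its median, against 373 as deposited. The medians were 9.21 on straw and 8.11 on pine, whereas the median of the differences was 0.21. Centring takes the gap between these medians from every difference, so the higher count follows from the centring itself. The mean of the 6 correlations of changes, 0.6492 as deposited, was 0.6595 after quantile normalisation and 0.6579 in the upper 75% of genes by mean level, and 0.6462 to 0.6543 when each maltose library was left out. The cause was not tested.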

Other observations

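In this part, the tests of the most frequent difference, of noise between pine libraries and of the scaling of pine were chosen after the results were seen, and the sets of media below were formed after the data were seen.

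Several sets of genes were shared by some media and set apart from others, with every direct test between them passed by limma. On cellulose, straw and aspen together, 58 of the 777 genes were higher than on both maltose and pine. Gene 837354 belonged to this set, at 12.18, 13.87 and 10.67 on these 3 solids against 3.92 on maltose and 5.53 on pine. The set held 36 genes after median centring and 37 after quantile normalisation. On the 3 plant materials together, 14 genes were higher than on maltose and cellulose, among them 677373, at 8.47 on straw, 11.74 on pine and 9.75 on aspen against 3.55 and 3.77. By the other scalings this set held 17 to 23 genes. Cellulose and straw shared 38 genes above the other 3 media, straw and aspen shared 26, among them 237425, and the 2 woods shared 7. By the other scalings these sets held 25 to 40, 17 to 20 and 5 to 9 genes. The sets overlap and cannot be added up.

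Genes 789979 and 804624, picked because they are listed at 0 on pine, had 0 reads in its 3 libraries, which allows up to 1.08 normalised counts (3 reads over the 3 libraries). Gene 789979 stood at 6.75 on cellulose, 3.70 on aspen, 2.19 on maltose and 1.32 on straw, and 804624 at 6.36 on straw, 4.87 on cellulose, 1.99 on aspen and 1.67 on maltose, so both were also low in other media. Gene 165303, picked after its values were seen, was too high on maltose to be tested: its deposited level was 14.87 there and 7.67 to 8.60 on pine, straw, aspen and cellulose.

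More genes were higher than lower on straw, cellulose and aspen than on maltose. Scaling of the libraries was first tested by centring each library on its median, and by that test, written before its result, the split turned, to 39.3% higher at the lowest. That outcome was the one predicted for scaling. It cannot decide, because such centring removes any difference between library medians, whatever its cause. After centring on the median difference from the gene means, 63%, 63.2% and 55.4% stayed higher on cellulose, straw and aspen. A second test, chosen after the first, goes against that prediction. In it, the most frequent difference to maltose over all listed genes lay at most 0.148 from 0 on the log2 scale. A shift of all genes would place it farther out. As most of the listed genes may have changed, neither test settles it, and whether genes outside the 949 listed show the same split cannot be told apart from the choice of genes, so scaling, that choice, the solid and, on cellulose and straw, the lower maltose all stay open.

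Fewer genes were higher than on maltose on pine (168) than on cellulose, straw or aspen. This pattern replaced an earlier idea, that fewer genes changed on pine, which the counts (315 on pine, 319 on cellulose) did not bear out. The median SD between pine libraries (0.16) was 0.934 times that on cellulose (0.17), the highest of the other solids. It was slightly above that on aspen. The median SD on straw was lower (0.13), but it comes from 2 libraries and is not directly comparable. Noise is argued against by the counts by size alone, which use no test. These gave 191 genes on pine against 268, 306 and 280 on cellulose, straw and aspen. The most frequent difference between pine and maltose was 0.076, but scaling stays open, since after median centring 153 genes were higher on pine and 148 on aspen, and after quantile normalisation 165 on each, although after centring on the median difference pine kept the fewest (162, against 208, 253 and 184 on cellulose, straw and aspen). A smaller response on pine of genes that rose on cellulose remains a candidate explanation: 65.3% of them were lower on pine by the direct test, and 53.4% to 62.1% under the other scalings, although these genes were chosen for high values on cellulose.

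Other groupings of the libraries were tried. For each of the 6 comparisons between media with 3 libraries, the labelled split was 1 of 10 possible, which is too few to judge chance. These labelled splits gave 319 (cellulose against maltose), 315 (pine against maltose), 348 (aspen against maltose), 325 (pine against cellulose), 252 (aspen against cellulose) and 283 (pine against aspen) calls by limma, and the highest other split gave 0. For the difference over all 5 media, 1 of 100 groupings, the labelled one, gave as many as 720 genes, and the highest of the others gave 173. Chance assignment of these 14 libraries to media is therefore unlikely there, but not excluded, since 1 of 100 is the lowest share that these groupings can give. Groupings that mix media also widen the spread within groups, which lowers their counts. Chance differences between single cultures stay open, if the replicates are technical.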
